A study of Mus musculus with 86 samples.

How the data were processed

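RNA was sequenced from the gastrocnemius and soleus of 43 mice per muscle in 9 groups, 86 libraries in all. Per the labels, RNA was taken with TRIzol, libraries were made with a strand-specific MGIEasy kit, and paired reads were sequenced on an MGI instrument. The deposited values are expected counts per gene symbol, which the authors made with FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 on the mouse build GRCm38, per the submitters' processing notes. Settings, the gene annotation, the strand setting and any filter are not stated. Of the values 92.0% were whole, and 18.5% of the non-zero ones were not whole, counted with a tolerance of 0. Each column of the table was matched to a sample by the name in its label. The labels name 1 batch for all samples and speak of 5 groups of mice in the protocol, while the samples form 9. DEX and non-treated mice were gavaged with buffer and the treated mice with extract or resveratrol in a cellulose vehicle, so a treatment cannot be told apart from its vehicle.

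Expected counts were rounded to whole numbers. Genes were kept with the edgeR function filterByExpr on the groups, which left 14484 genes in GA, 14811 in SO and 15327 in the fit of both muscles. Libraries were scaled with TMM. Each muscle had 1 fit over its 9 groups, and comparisons of the muscles used 1 fit over all 86 libraries. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 gave p values, adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. The changed genes of 3 comparisons per muscle come from contrasts of several groups, namely the mean of the 6 extract groups against DEX, the 3 higher against the 3 lower doses, and an F test between the extracts. Differences between the muscles are interaction contrasts. SEs of log2 fold changes come from the same fits. Gene lists, 24 of pathways and 12 of cell types, and a panel of 16 genes were fixed before the data were examined, as were the groups, comparisons, tests, rule for naming genes and first alternatives. Lists were tested with camera of limma 3.58.1 on the counts of the fit at a preset correlation of 0.01, and again with an estimated correlation. Camera p values were adjusted over the 36 lists of a comparison. A count adjusted over the list alone adjusts over its measured members.

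Genes named were, for DEX against non-treated, the 8 largest rises and falls and, for other comparisons, the 5 largest (for the F tests the 6 smallest p). They had to pass, reach a mean of 5 CPM, show no overlap between the libraries of the groups and not be predicted genes. The panel genes and up to 2 members per list and direction were added. From this pool mainly genes whose call held when any 1 library was left out were given in the text, a choice made after their values were seen, and genes whose call rested on 1 library are given with that library. Positions are from GENCODE vM21 on GRCm38. Genes withheld for evaluation are not reported here. Of 142 genes named with a position in the annotation, 14 share over 10% of their 31-base words with another gene, and 37 have exons over exons of a gene on the other strand, whose reads cannot be told apart if the counting ignored strand.

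The DEX score of a library is the mean log2 CPM (prior count of 2) of genes raised, less that of genes lowered, by the mean of the 8 DEX-treated groups against non-treated, with the non-treated mean set to 0. Groups were compared with a two-sided exact permutation test. Total counts per library were 18.8 to 34.6 M, and the 10 highest genes took 9.8% to 29.1% of the counts in GA and 8% to 33.7% in SO. Tests were tested on simulated data with known changes in DEX against non-treated. In GA 52.2%, 79.1% and 100% of genes changed 1.5-, 2- and 4-fold were recovered among 14421 genes, and in SO 62.7%, 91% and 98.5% among 14700. Of unchanged genes 0.05% and 0.02% were called.

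Alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, fits of only the groups compared, the mouse number as a block, leaving out each library in turn, other genes for the score, and for the opposite calls a division of the DEX libraries. After the data were seen, fits without libraries that stood apart and fits with a set term were added. The sets follow the listed order of the libraries and are not in the labels. Each comparison was also run on up to 100 splits of its libraries, the real one included. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No raw reads were available, so alignment and strand could not be checked.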

Results

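RNA-seq counts were available for 2 leg muscles of male C57BL/6N mice, the gastrocnemius (GA), a mixed muscle rich in fast fibres, and the soleus (SO), rich in slow fibres. Dexamethasone (DEX), a synthetic glucocorticoid that causes muscle atrophy, was injected at 25 mg/kg each day for 10 days in all groups except the non-treated one. Treated mice also received by gavage Jakyak-gamcho-tang (JGT), an extract of peony root and liquorice root, or resveratrol (RSV), a plant polyphenol, at 200 mg/kg. The extracts JGT02, JGT03 and JGT04 held peony and liquorice at 2:1, 1:1 and 1:2, and each was given at 100 or 400 mg/kg. Each muscle had 43 libraries in 9 groups. The DEX group and the JGT04 group at 400 mg/kg had 4 mice and the other 7 groups had 5. Total counts per library ran from 22.3 to 32.1 M (mega counts) in GA and from 18.8 to 34.6 M in SO, with a median of 27.5 M over the 86 libraries. Of 42807 genes listed, 13515 had no count in any library. Values below are CPM, counts scaled to the TMM-adjusted total of the library, as mean ± SD, log2 fold changes ± standard error (SE), and p values of the edgeR quasi-likelihood test, Benjamini-Hochberg adjusted over all genes tested, unless another test is named. P values of the 36 gene lists are from camera with a preset correlation, adjusted over the lists of a comparison. Of 864 list tests 263 passed, and 1 of these held with an estimated correlation, which is printed beside each list.

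In 2 libraries, GA JGT02 100 mg/kg mouse 1 and SO JGT02 100 mg/kg mouse 5, the embryonic myosin gene Myh3 reached 1240 and 1060 CPM, against at most 25.9 in the other GA and 122 in the other SO libraries. Their expression profiles correlated with those of their own groups at medians of 0.7314 and 0.6509. Their differences from the mean of the other libraries of their group correlated with each other at 0.867. In another library, labelled SO JGT02 400 mg/kg mouse 1, Mss51, a fast-fibre gene, stood at 544 CPM, where other SO libraries had at most 12.2. The slow myosin gene Myh7 stood at 14.4 CPM in it and at 27.3 in SO JGT02 100 mg/kg mouse 5, where the other SO libraries had at least 4180. Without these 3 libraries the common dispersion fell from 0.0379 to 0.00699 in GA and from 0.0585 to 0.0187 in SO. Counts of changed genes without them are marked "without the 3 libraries". They are given beside many of those from all libraries, and for every comparison in the section on processing. Inside GA JGT04 100 mg/kg, Cebpb, a transcription factor gene of the stress and glucocorticoid response, lay between 15.3 and 16.2 CPM in mice 1 to 3 and between 23.3 and 23.4 in mice 4 and 5. Inside SO JGT02 400 mg/kg it lay between 29.1 and 36.8 in mice 1 to 3 and between 15.6 and 18 in mice 4 and 5. In the listed order of the libraries these breaks divide the 86 into sets of 32, 28 and 26. DEX and non-treated libraries of a muscle share a set. GA JGT04 400 mg/kg and RSV, and SO JGT03, JGT04 and RSV, were in a later set than their DEX group, and counts with the set as a term in the model are given beside theirs.

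**Figure D1:**
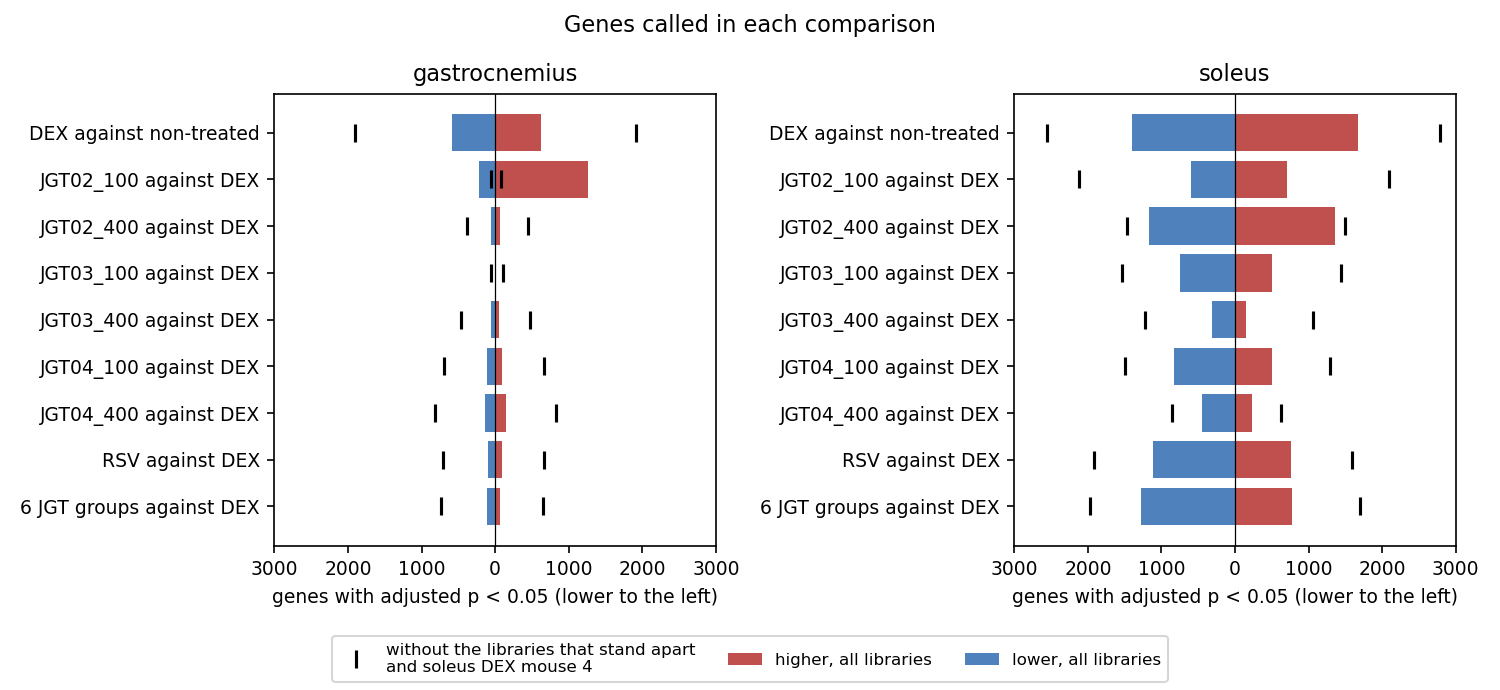
Genes with an adjusted p below 0.05 in each comparison (vertical axis), with higher genes to the right and lower genes to the left of 0 (horizontal axis, number of genes); bars are from all libraries and ticks from the fit without the 3 libraries and SO DEX mouse 4. In soleus DEX changed 3079 genes, and in gastrocnemius 1214.

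The comparison of the muscles in non-treated mice shows what each library type holds. SO carried more of the slow-fibre transcripts: troponins Tnnc1, Tnnt1 and Tnni1 were 28.6-, 28.5- and 26.9-fold higher (Tnnt1 log2 4.83 ± 0.45, adjusted p = 1.95e-14, n = 5 and 5), and Myoz2 12.1-fold. Sln, a regulator of the calcium pump that the lists hold as a fast-fibre gene, was 43.4-fold higher in SO. The slow myosin Myh7 was at 7216 ± 498 CPM in SO and 383 ± 50.2 in GA, and the fast IIa myosin Myh2 was 4.22-fold higher in SO. GA held more of the fast IIb myosin Myh4, 50452 ± 3523 against 279 ± 468 CPM, of Mss51 (129.51 against 0.96 CPM), of myostatin, Mstn, which limits muscle mass (log2 -5.84 ± 0.56), and of the glycolytic regulator Pfkfb3 (log2 -4.59 ± 0.43). All 19 slow-fibre contractile genes were higher in SO (adjusted p = 3.95e-19, adjusted p = 0.117 with an estimated correlation), and 18 of 20 fast-fibre genes were lower and 1, Sln, higher (adjusted p = 2.67e-09, adjusted p = 0.475 with an estimated correlation). Of 35 fatty acid genes 31 were higher and none lower, among them Lpl (log2 2.46 ± 0.26) and Dgat2 (2.57 ± 0.27) (adjusted p = 3.79e-14, adjusted p = 0.475 with an estimated correlation). Of 26 glycolysis genes 19 were lower and 1 higher, with Gpd1 at log2 -3.30 ± 0.33 and Phkb at -2.71 ± 0.27 (adjusted p = 1.22e-09, adjusted p = 0.5 with an estimated correlation). The counts adjusted over the list alone were 19 and 0, 1 and 18, 32 and 0, and 2 and 20, higher and lower. The ubiquitin ligase genes Fbxo32 and Trim63 were lower in SO by log2 -0.61 ± 0.20 and -0.58 ± 0.12, and without GA non-treated mouse 5 Fbxo32 did not pass (-0.37, adjusted p = 0.144). In total 7016 of 15327 genes differed, 3477 with the set as a term, where the median SE of the 7016 was 0.249 in place of 0.143 and 99.6% kept their sign. The myosins Myh4, Myh1, Myh2 and Myh7 share 30.4%, 37.9%, 32.8% and 22.9% of their 31-base words with other genes, mainly each other or Myh6, so their split of reads is less certain. Exons of Fbxo32, Cebpb and Eng lie over exons of genes on the other strand, and the strand setting of the counting is not stated.

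DEX against non-treated mice is the comparison that measures the atrophy model. In GA the iron-binding acute phase gene Lcn2 (GRCm38 chromosome 2, 32384633 to 32388252) rose 48-fold, from 1.68 ± 1.45 to 79.8 ± 9.06 CPM (log2 5.58 ± 0.31, adjusted p = 5.67e-16, n = 4 and 5). Pnmt, an enzyme of adrenaline synthesis induced by glucocorticoids, rose 16.6-fold, the methyl-group enzyme gene Gnmt 7.76-fold, and the chromatin remodeller gene Chd9 4.85-fold. The acute phase gene Orm1 rose 14.7-fold, although it shares 27.5% of its 31-base words with Orm2. The antigen presentation genes H2-Aa, H2-Ab1 and Cd74 fell by log2 2.90 ± 0.67, 2.69 ± 0.61 and 2.78 ± 0.61. Fbxo32 and Trim63, the ubiquitin ligase genes commonly used as atrophy markers, fell. Fbxo32 (chromosome 15, 58175879 to 58214932) went from 519 ± 214 to 239 ± 71.0 CPM (adjusted p = 0.000292), and Trim63 from 199 ± 55.4 to 114 ± 11.6 CPM (adjusted p = 2.85e-05). The ubiquitin ligase gene Nedd4 rose (log2 0.28 ± 0.06). Of the 32 genes of the atrophy list 3 rose, 5 fell and 24 did not pass, and the list as a group did not pass (adjusted p = 0.321).

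In the same GA comparison the circadian clock genes moved apart, 8 of 20 up and 3 down (13 and 3 adjusted over the list alone; adjusted p = 3.35e-06, adjusted p = 0.433 with an estimated correlation). Per2 and Dbp, of the repressor arm and its output, rose by log2 1.80 ± 0.21 and 1.57 ± 0.25, and the activators Arntl and Npas2 fell by 2.18 ± 0.22 and 3.21 ± 0.53. Adipocyte markers rose, 8 of 14 with 1 down, among them the lipid droplet genes Cidec (1.99 ± 0.29) and Cidea (1.47 ± 0.25) (10 and 1 adjusted over the list alone; adjusted p = 1.79e-07, adjusted p = 0.394 with an estimated correlation). Tendon cell markers fell, 8 of 13, among them Chad (-1.66 ± 0.33) and Cilp2 (-2.22 ± 0.31) (10 down and 1 up adjusted over the list alone; adjusted p = 5.5e-07, adjusted p = 0.394 with an estimated correlation). Of 38 extracellular matrix genes 5 fell, including the protease Mmp2 (-0.98 ± 0.22) (15 adjusted over the list alone; adjusted p = 1.03e-06, adjusted p = 0.809 with an estimated correlation). Of 15 endothelial markers 5 fell, including Vwf (-0.58 ± 0.13) (8 adjusted over the list alone; adjusted p = 2.6e-05, adjusted p = 0.405 with an estimated correlation). Of 30 growth signalling genes 2 rose and 3 fell (adjusted p = 0.321 for the list). Igf1r, the receptor of insulin-like growth factor, rose by 0.43 ± 0.09, the translation repressor gene Eif4ebp1 by 0.47 ± 0.10, and Igfbp5 fell by 1.03 ± 0.21. The 76 nuclear oxidative phosphorylation genes were lower as a group at a median of -0.18 with 3 passing (adjusted p = 7.26e-06, adjusted p = 0.894 with an estimated correlation). Of 30 interferon response genes 3 fell, including Rsad2 (-1.65 ± 0.33) (4 adjusted over the list alone; adjusted p = 0.0292, adjusted p = 0.894 with an estimated correlation). Without the 3 libraries this list did not pass (adjusted p = 0.0817). In all 1214 genes changed, 624 up and 590 down, and 3811 without the 3 libraries. Leaving out 1 library at a time gave 871 to 1103. Among the other panel genes none passed: Foxo1, Foxo3, Klf15, Fkbp5, Tsc22d3, Pdk4, Mstn, Igf1, Ppargc1a, Sirt1, Myh7, Myh2, Myh1 and Myh4 lay between log2 -1.09 (Pdk4) and 0.72 (Igf1).

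In SO, DEX raised Lcn2 25.9-fold, from 1.13 ± 0.55 to 29.3 ± 15.5 CPM (log2 4.69 ± 0.33, adjusted p = 1.03e-12, n = 4 and 5), the haemoglobin-binding acute phase gene Hp 11.3-fold, the adipocyte hormone gene Lep 10.6-fold and Cidec 9.28-fold. Arntl fell by 2.98 ± 0.22 (adjusted p = 1.48e-12), the carnitine transporter gene Slc16a9 by 1.74 ± 0.16, the lipid synthesis gene Gpam by 1.60 ± 0.35, and the mitochondrial genes Ucp3 and Taco1 by 1.59 ± 0.36 and 1.47 ± 0.26. Pdk4, which limits glucose oxidation, fell from 587 ± 301 to 143 ± 66.3 CPM (log2 -2.03 ± 0.40, adjusted p = 0.000753). Fbxo32 fell from 353 ± 109 to 178 ± 40.2 CPM (adjusted p = 0.00237), and the muscle ligase gene Trim55 by 0.83 ± 0.14. Trim63 fell by 0.50 ± 0.14 (adjusted p = 0.0098), but not without DEX mouse 2 (-0.38, adjusted p = 0.0543). Of 32 atrophy list genes 9 fell and 3 rose (10 and 4 adjusted over the list alone; adjusted p = 0.0057, adjusted p = 0.564 with an estimated correlation). The macrophage gene Chil3 rose 56.3-fold and the matrix protease gene Mmp19 8.36-fold, but without DEX mouse 4 these were 1.68 and 0.93 in log2 and did not pass (adjusted p = 0.265 and 0.369). Chil3 also shares 41.5% of its 31-base words with other genes.

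Ribosomal protein genes rose in SO, 34 of 48 and none down, at a median of 0.38, with Rps28 at 0.59 ± 0.11 and Rps14 at 0.52 ± 0.10, which share 11.8% and 11.7% of their 31-base words with other genes (44 adjusted over the list alone; adjusted p = 2.16e-15, adjusted p = 0.564 with an estimated correlation). Schwann cell and nerve markers rose, 13 of 14 at a median of 1.59, among them Sox10 (1.72 ± 0.35) and S100b (1.87 ± 0.41) (14 adjusted over the list alone; adjusted p = 4.32e-06, adjusted p = 0.564 with an estimated correlation). Adipocyte markers rose, 9 of 14, with Thrsp at 2.02 ± 0.44 (10 adjusted over the list alone; adjusted p = 0.000256, adjusted p = 0.564 with an estimated correlation). Endothelial markers went up in 7 of 15, with the endothelial receptor gene Eng at 1.00 ± 0.13, and down in 1, Aplnr, at -1.46 ± 0.29 (8 and 1 adjusted over the list alone; adjusted p = 0.000597, adjusted p = 0.564 with an estimated correlation). Of 21 cholesterol synthesis genes 8 rose, Lss by 0.82 ± 0.18 (9 adjusted over the list alone; adjusted p = 0.000597, adjusted p = 0.564 with an estimated correlation). Of 35 fatty acid genes 7 fell and 2 rose (14 and 2 adjusted over the list alone; adjusted p = 0.000597, adjusted p = 0.882 with an estimated correlation). Of 33 autophagy and lysosome genes 6 fell, including the lysosomal membrane gene Lamp1 (-0.34 ± 0.07) and Calcoco1 (-0.58 ± 0.13) (5 adjusted over the list alone; adjusted p = 0.00123, adjusted p = 0.564 with an estimated correlation). Of 28 stress response genes 10 rose and 1 fell, with the serine synthesis gene Psat1 at 1.66 ± 0.30 (11 and 1 adjusted over the list alone; adjusted p = 0.000597, adjusted p = 0.564 with an estimated correlation). Without the 3 libraries and DEX mouse 4 this list missed the threshold (adjusted p = 0.0508). Of 20 clock genes 7 rose and 4 fell, Per2 by 2.22 ± 0.16 and Npas2 by -2.37 ± 0.38, which as a group did not pass (adjusted p = 0.12). In all 3079 genes changed, 1676 up and 1403 down. Without DEX mouse 4 there were 1981 and without the 3 libraries 6353. Of the other panel genes none passed. Myh4 had the widest spread at 2.09 ± 1.24. Without non-treated mouse 1, which held 1138 CPM of it, Myh4 passed at 4.07 (adjusted p = 0.0383). Foxo3 passed without DEX mouse 1 (-0.38, adjusted p = 0.0131).

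The difference between these changes, SO minus GA, gives the genes whose change with DEX differed between the muscles. The RNA-binding protein gene Cpeb1 differed by log2 2.21 ± 0.17 (adjusted p = 3.3e-16), rising more or falling less in SO. The oxygen sensor gene Egln3 differed by -2.14 ± 0.19 (adjusted p = 3.96e-13), Gpam by -1.88 ± 0.36, and Smad3, of the transforming growth factor pathway, by -1.24 ± 0.19. The ligase genes Trim55 and Nedd4 differed by -0.93 ± 0.19 and -0.59 ± 0.11. Schwann cell and nerve markers were higher in 11 of 14, with the myelin gene Mag at 2.23 ± 0.52 (14 adjusted over the list alone; adjusted p = 4.29e-08, adjusted p = 0.535 with an estimated correlation). Endothelial markers were higher in 9 of 15, Eng at 0.80 ± 0.16 and Esam at 0.77 ± 0.14 (13 adjusted over the list alone; adjusted p = 4.07e-10, adjusted p = 0.247 with an estimated correlation). Of 38 matrix genes 4 were higher, with the protease inhibitor gene Timp3 at 0.99 ± 0.20 (adjusted p = 0.000637, adjusted p = 0.797 with an estimated correlation). Autophagy genes were lower in 3 of 33 (6 adjusted over the list alone; adjusted p = 1.6e-05, adjusted p = 0.535 with an estimated correlation). In all 1282 of 15327 genes differed, 584 higher and 698 lower. With DESeq2 size factors the split was 512 and 1046. Mybph, which encodes myosin-binding protein H, differed by 4.05 ± 1.16, but without SO DEX mouse 4 did not pass (2.36, adjusted p = 0.201). Ucp3 (-1.54 ± 0.47) did not pass without GA DEX mouse 4 (-1.35, adjusted p = 0.0675) or SO non-treated mouse 4 (-1.21, adjusted p = 0.0857).

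**Figure D2:**
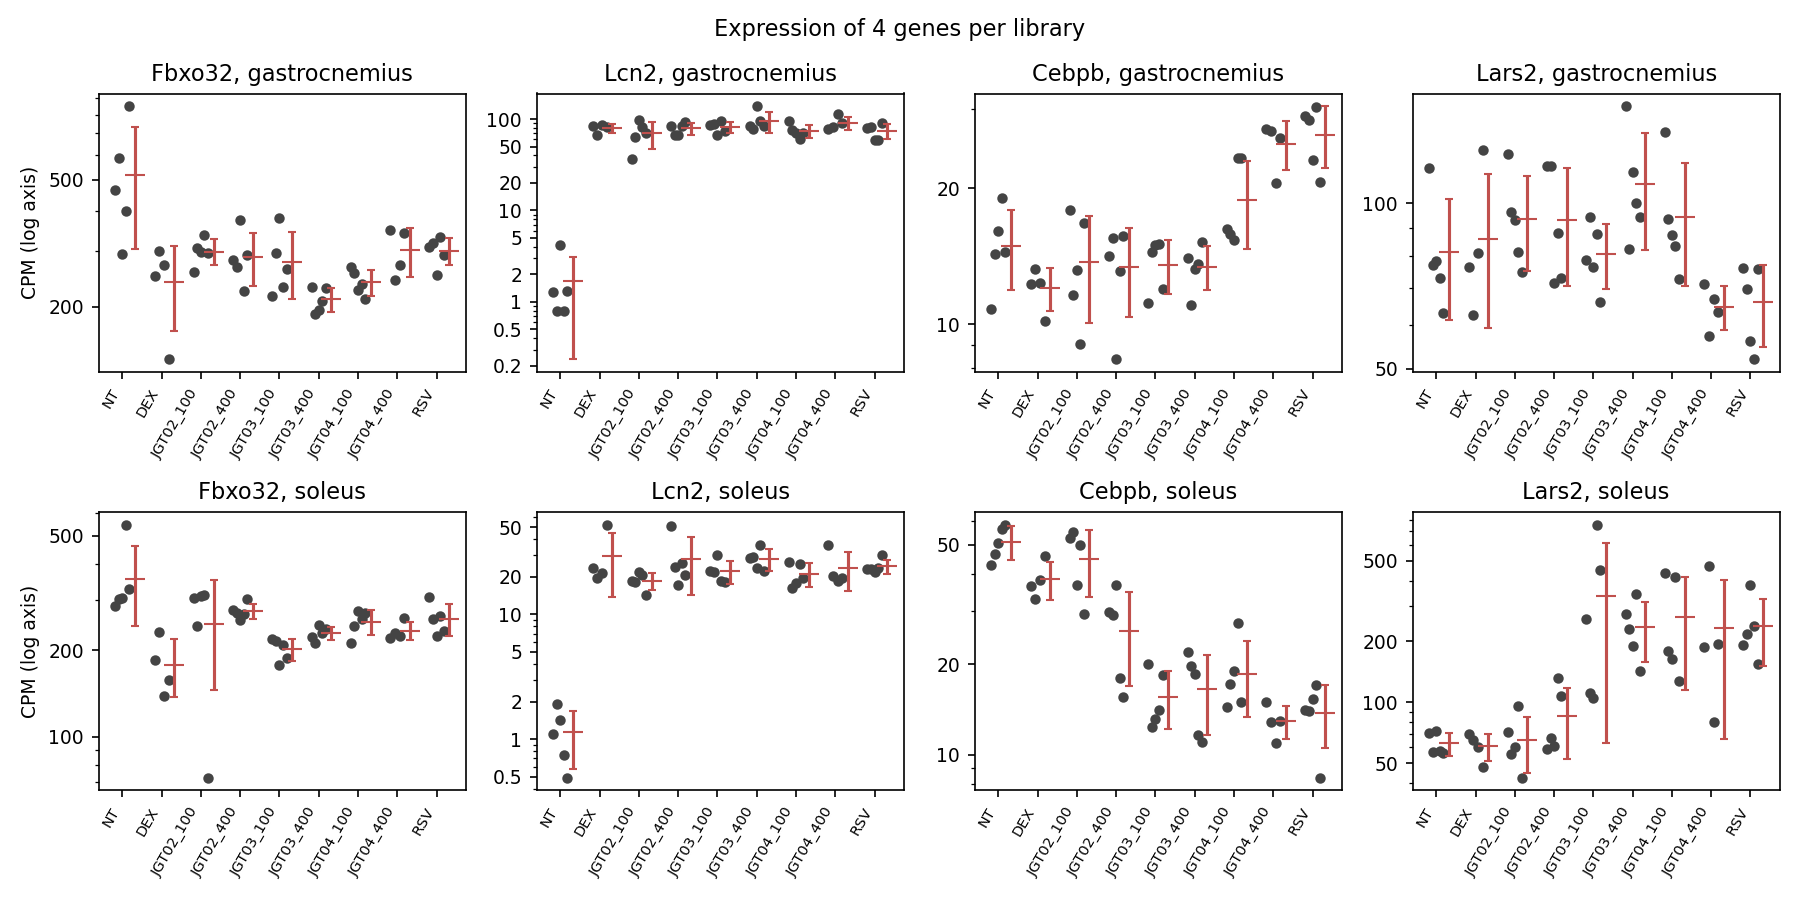
CPM of 4 genes in each library (points; vertical axis, log scale) by group (horizontal axis), with mean and SD (red), in gastrocnemius and soleus. Fbxo32 is lower in the DEX groups (239 CPM in gastrocnemius, 178 in soleus) than in the non-treated groups (519 and 353).

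Each treatment was compared with DEX alone to ask which genes it moved in atrophying muscle. All these comparisons of a muscle use the same 4 DEX libraries, so a change seen with several treatments is not an independent repeat. In GA with JGT02 at 400 mg/kg the glycogen-targeting phosphatase gene Ppp1r3c fell by log2 1.64 ± 0.23, from 217 ± 65.4 to 69.9 ± 8.53 CPM (adjusted p = 0.000133, n = 5 and 4). The glucocorticoid target Fkbp5 fell from 77 ± 5.53 to 44.0 ± 2.80 CPM (adjusted p = 0.012), the nuclear protein gene Banp by 1.08 ± 0.17, and the long non-coding genes Mir22hg and Foxo6os rose by 0.84 ± 0.12 and 0.79 ± 0.15. Of 19 slow-fibre genes none passed over all genes and 3 rose adjusted over the list alone, with a median of 0.46 (adjusted p = 4.48e-06, adjusted p = 0.223 with an estimated correlation). On a scale of these genes with the GA median at 0 and the SO median at 1, mice 1 and 2 stood at 0.279 and 0.13, but mice 3 to 5 at -0.001 to 0.02, where DEX mice ran from -0.124 to 0.019. Endothelial markers fell in 2 of 15 (5 adjusted over the list alone; adjusted p = 3.14e-08, adjusted p = 0.149 with an estimated correlation). Of 38 glucocorticoid receptor targets 1 fell (3 adjusted over the list alone; adjusted p = 0.00543, adjusted p = 0.149 with an estimated correlation). In all 117 genes changed, 823 without the 3 libraries. The count was 71, 54 and 39 without DEX mice 1, 2 and 4, and 61, 63, 52 and 67 without treated mice 2, 3, 4 and 5. With JGT02 at 100 mg/kg 1478 genes changed, 1263 up, and these rested on mouse 1. Without it 139 changed, 50 of them among the 1478. The acetylcholine receptor gene Chrnd, raised in denervated or regenerating fibres, went from log2 2.98 ± 0.63 to 0.37 without that mouse (adjusted p = 0.295). Macrophage markers were up in 13 of 14 at a median of 2.89 (adjusted p = 0.000139, adjusted p = 0.549 with an estimated correlation), and at -0.07 without it. Sesn1, a stress-induced inhibitor of growth signalling, rose by 0.71 ± 0.13 (adjusted p = 0.0064), and by 0.63 without mouse 1 (adjusted p = 0.00777). The count was 336, 683, 120 and 216 without DEX mice 1 to 4 and 2376 to 2902 without treated mice 2, 3, 4 or 5.

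With JGT03 at 100 mg/kg 3 genes changed in GA. The growth factor receptor gene Met rose by 0.38 ± 0.06, from 17.4 ± 1.57 to 22.7 ± 1.16 CPM (adjusted p = 0.000538, n = 5 and 4). The acyl-CoA enzyme gene Acot2 rose by 1.25 ± 0.21, although it shares 37.3% of its 31-base words with other genes, and the nuclear receptor gene Nr4a3 fell by 2.13 ± 0.39. Acot2 and Nr4a3 did not pass without DEX mouse 1 (adjusted p = 0.104 each) or treated mouse 2 (0.0524 each), and Nr4a3 not without DEX mouse 4 (0.393) or treated mice 3, 4 or 5 (0.0697, 0.0783 and 0.0532). The slow-fibre list was higher as a group, with a median of 0.27 and none passing (adjusted p = 0.00029, adjusted p = 0.674 with an estimated correlation). Without the 3 libraries 169 genes changed. With JGT03 at 400 mg/kg the integrin gene Itgb6 rose by 0.77 ± 0.10 (adjusted p = 3.86e-05, n = 5 and 4), the arrestin gene Arrdc3 by 0.86 ± 0.15 and the transcriptional repressor gene Zfp503 by 0.86 ± 0.16. Ppp1r3c fell by 1.22 ± 0.23, Banp by 1.07 ± 0.17 and the retinoid enzyme gene Dhrs3 by 0.71 ± 0.13. Of 15 endothelial markers 1 fell (5 adjusted over the list alone; adjusted p = 0.000139, adjusted p = 0.763 with an estimated correlation). In all 98 genes changed, 936 without the 3 libraries. The count was 63, 33, 61 and 37 without DEX mice 1 to 4 and 47, 40, 52 and 59 without treated mice 1 to 4.

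With JGT04 at 100 mg/kg Arrdc3 rose by 1.05 ± 0.15 in GA, from 25.4 ± 7.30 to 52.6 ± 9.54 CPM (adjusted p = 7.93e-05, n = 5 and 4), Zfp503 by 0.96 ± 0.16, Mir22hg by 0.87 ± 0.12 and the ubiquitin ligase gene Fbxo21 by 0.47 ± 0.08. Ppp1r3c fell by 1.44 ± 0.23, Banp by 1.15 ± 0.17, and the clock genes Nr1d1 and Clock by 1.08 ± 0.22 and 0.42 ± 0.07. These passed with the set as a term too. Fkbp5, which fell by 0.88 ± 0.17 (adjusted p = 0.003), did not (-0.76 ± 0.20, adjusted p = 0.0605). Endothelial markers fell in 1 of 15 (5 adjusted over the list alone; adjusted p = 4e-06, adjusted p = 0.747 with an estimated correlation). Of 27 stress response genes 2 fell (3 adjusted over the list alone; adjusted p = 0.000613, adjusted p = 0.985 with an estimated correlation). In all 200 genes changed, 90 with the set as a term and 1350 without the 3 libraries. Without DEX mice 2 and 4 and treated mice 3 and 5 there were 111, 109, 100 and 85. With JGT04 at 400 mg/kg Arrdc3 rose by 1.41 ± 0.16 (adjusted p = 1.84e-06, n = 4 and 4), Cebpb by 1.06 ± 0.19 and the glucose transport gene Tbc1d1 by 0.97 ± 0.15. Ppp1r3c fell by 1.87 ± 0.25, Nr4a3 by 2.66 ± 0.44, Fkbp5 by 1.14 ± 0.18, Clock by 0.48 ± 0.07 and Eng by 0.62 ± 0.11. Of 15 endothelial markers 4 fell (8 adjusted over the list alone; adjusted p = 2.65e-10, adjusted p = 0.122 with an estimated correlation). The 38 matrix genes were lower as a group, with a median of -0.45 and none passing (adjusted p = 0.000122, adjusted p = 0.722 with an estimated correlation). In all 295 genes changed. With the set as a term none passed by edgeR (641 at an unadjusted p below 0.05), and 52 without the 3 libraries. For the 295 the median log2 size went from 0.47 to 0.42 and the median SE from 0.11 to 0.179. Ppp1r3c stood at -1.78 ± 0.40 and Cebpb at 0.50 ± 0.28. The count was 169 and 118 without DEX mice 2 and 4 and 137, 161, 194 and 151 without treated mice 1 to 4.

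Averaged over the 6 extract groups in GA, Ppp1r3c fell by 1.33 ± 0.16 (adjusted p = 4.99e-06, n = 29 and 4), Fkbp5 by 0.69 ± 0.13 (adjusted p = 0.002), the clock repressor gene Nfil3 by 0.59 ± 0.11 and Eng by 0.45 ± 0.08. Zfp503 and Arrdc3 rose by 0.78 ± 0.14 and 0.75 ± 0.13. The 6 passed with the set as a term too, Fkbp5 at -0.62 ± 0.14 (adjusted p = 0.0247). Endothelial markers fell in 2 of 15 (5 adjusted over the list alone; adjusted p = 1.72e-07, adjusted p = 0.409 with an estimated correlation). In all 182 genes changed, 70 up and 112 down. There were 99 with the set as a term, 1381 without JGT02 100 mg/kg mouse 1, and 99, 84, 112 and 48 without DEX mice 1 to 4. With RSV in GA, Arrdc3 rose by 1.03 ± 0.15 (adjusted p = 0.000202, n = 5 and 4), Cebpb by 1.13 ± 0.18, the stress gene Gadd45b by 1.04 ± 0.18 and the ubiquitin ligase gene Cblb by 0.38 ± 0.08. Ppp1r3c fell by 1.46 ± 0.23, the nicotinamide riboside kinase gene Nmrk2 by 2.11 ± 0.34 and Clock by 0.43 ± 0.07. Fkbp5 fell by 0.76 ± 0.17 (adjusted p = 0.0128), but not without RSV mouse 1 (-0.69, adjusted p = 0.0564). Of 15 endothelial markers 4 fell, Eng by 0.55 ± 0.10 (6 adjusted over the list alone; adjusted p = 5.12e-09, adjusted p = 0.213 with an estimated correlation). In all 199 genes changed with RSV, and 1367 without the 3 libraries. With the set as a term 1 changed, where the median log2 size of the 199 went from 0.42 to 0.36 and the median SE from 0.0957 to 0.162. The count was 107 and 96 without DEX mice 2 and 4 and 111, 117 and 131 without RSV mice 1, 2 and 3.

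The higher dose was compared with the lower over the 3 extracts. In GA 29 genes differed: Foxo6os and Arrdc3 were higher at 400 mg/kg by 0.61 ± 0.08 (adjusted p = 5.6e-05) and 0.54 ± 0.08, also with the set as a term (0.58 ± 0.09 and 0.49 ± 0.09). The transcription factor gene Foxo6 and the signalling inhibitor gene Smad7 were higher by 0.45 ± 0.09 and 0.38 ± 0.07 and Dhrs3 was lower by 0.40 ± 0.07. These 3 did not pass with the set as a term (adjusted p = 0.142, 0.0949 and 0.0779), when 4 genes differed. Matrix genes were lower as a group at a median of -0.50 (adjusted p = 1.62e-14, adjusted p = 0.667 with an estimated correlation), which was -0.16 without JGT02 100 mg/kg mouse 1, and macrophage markers were at -1.10 (adjusted p = 5.85e-07, adjusted p = 0.667 with an estimated correlation) and -0.11 without it. The count was 243 without that mouse, and 9 to 66 without 1 of the other 28, with the lowest for JGT04 400 mg/kg mouse 1. By DESeq2 it was 118, 58 up and 60 down. In SO no gene differed between the doses by edgeR, 1999 had an unadjusted p below 0.05, and DESeq2 called none. Between the extracts as a whole Arrdc3, Cebpb, the chromatin gene Bcl7a and Foxo6 were among 109 genes that differed in GA (Arrdc3 adjusted p = 5.78e-05). Cebpb, the neuronal regulator gene Auts2, the intermediate filament gene Sync and the protein quality gene Edem3 were among 1775 in SO (Cebpb adjusted p = 1.67e-05). With the set as a term edgeR called 0 in GA (1349 at an unadjusted p below 0.05) and 4 in SO. GA JGT04 at 400 mg/kg and the JGT03 and JGT04 libraries of SO lie in a later set than DEX, as do mice 4 and 5 of GA JGT04 at 100 mg/kg. Without 1 JGT02 100 mg/kg mouse (1 to 5) the GA count was 306, 578, 805, 622 and 726. Without another mouse it was as low as 15 (JGT04 400 mg/kg mouse 1), and without SO JGT02 100 mg/kg mouse 5 the SO count was 3651.

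In SO with JGT02 at 100 mg/kg, all in the set of the DEX libraries, 13 of 15 endothelial markers fell against DEX alone at a median of -0.70 (adjusted p = 1.47e-21, adjusted p = 0.0147 with an estimated correlation). It was the 1 of 864 list tests to pass with an estimated correlation. The correlation was estimated only in the fit of all libraries, which holds mouse 5 of this group. The adjustment covers the lists of 1 comparison and not all 864 tests. Eng fell from 137 ± 32 to 70.8 ± 4.58 CPM (log2 -0.95 ± 0.13, adjusted p = 4.45e-05, n = 5 and 4), Esam by 0.72 ± 0.11, the basement membrane gene Tinagl1 by 1.24 ± 0.15 (adjusted p = 3.36e-06) and the vasoconstrictor gene Edn1 by 1.49 ± 0.25. The ligase genes Nedd4 and Trim55 rose by 0.50 ± 0.09 and 0.68 ± 0.14. Of 33 autophagy genes 6 rose, among them Lamp1 (0.35 ± 0.07) (10 adjusted over the list alone; adjusted p = 0.000673, adjusted p = 0.542 with an estimated correlation). Markers of Schwann cells and nerve fell in 6 of 14 at a median of -1.33 (12 adjusted over the list alone; adjusted p = 1.98e-06, adjusted p = 0.542 with an estimated correlation). The oxidative phosphorylation list fell as a group with 4 of 76 passing (adjusted p = 4.43e-12, adjusted p = 0.971 with an estimated correlation) and did not pass without the 3 libraries (adjusted p = 0.817). The rises of genes of regenerating fibres shrank without mouse 5. The neonatal myosin Myh8, which shares 18.6% of its 31-base words with other genes, rose by 4.97 ± 1.00, and without it by 0.48 without passing (adjusted p = 0.33). Capn6 and Chrna1 shrank from 3.60 ± 0.69 and 1.47 ± 0.34 to 0.72 and 0.41 without the 3 libraries and still passed (adjusted p = 0.00164 and 0.00466). In all 1306 genes changed, 5252 without the 3 libraries. There were 590 without DEX mouse 3 and 4631 without treated mouse 5. In a fit of only these 2 groups edgeR called none.

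With JGT02 at 400 mg/kg 13 of 15 endothelial markers fell against the same DEX libraries, Eng by 1.16 ± 0.13 (adjusted p = 3.9e-07, n = 5 and 4) and Pecam1 by 0.74 ± 0.12 (14 adjusted over the list alone; adjusted p = 3.42e-13, adjusted p = 0.144 with an estimated correlation). The lubricin gene Prg4 fell by 2.55 ± 0.64. Of 38 matrix genes 6 fell, including the basement membrane collagen gene Col4a2 by 1.13 ± 0.18 (5 adjusted over the list alone; adjusted p = 1.71e-05, adjusted p = 0.734 with an estimated correlation). Autophagy genes rose in 8 of 33, Lamp1 by 0.34 ± 0.07 (11 adjusted over the list alone; adjusted p = 9.76e-06, adjusted p = 0.515 with an estimated correlation), and Trim55 rose by 0.75 ± 0.14. These single genes passed with the set as a term too. Glycolysis genes rose in 14 of 26 with 1 down, at a median of 0.63 (18 and 1 adjusted over the list alone; adjusted p = 6e-07, adjusted p = 0.734 with an estimated correlation), which was 0.28 without the 3 libraries. Mss51 and Mstn rose by 5.95 ± 1.33 and 2.96 ± 0.74, and without mouse 1 did not pass (1.45, adjusted p = 0.296, and 0.76, adjusted p = 0.357). The glucocorticoid target Tsc22d3 rose by 0.96 ± 0.19 and by 0.52 without the 3 libraries. Fbxo32 rose by 0.62 ± 0.22 at an adjusted p of 0.0482, which ran from 0.0513 to 0.15 when 1 DEX mouse (1, 3 or 4) or 1 treated mouse was left out. In all 2532 genes changed, 4449 without the 3 libraries. There were 2098 with the set as a term, 1412 without DEX mouse 4, 1168 without treated mouse 1 and 490 in a fit of only these 2 groups.

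With JGT03 at 100 mg/kg the mitochondrial leucyl-tRNA synthetase gene Lars2 rose in SO from 60.7 ± 9.34 to 336 ± 274 CPM (log2 2.47 ± 0.48, adjusted p = 0.00134, n = 5 and 4), the lysosomal transporter gene Slc46a3 by 0.93 ± 0.14 (adjusted p = 6.58e-05) and Ipp by 0.79 ± 0.15. Nerve and Schwann cell markers fell in 11 of 14 at a median of -1.74, among them Mag (-1.94 ± 0.44; 14 adjusted over the list alone; adjusted p = 5.52e-09, adjusted p = 0.62 with an estimated correlation). Endothelial markers fell in 6 of 15, Eng by 0.96 ± 0.13 (9 adjusted over the list alone; adjusted p = 5.52e-09, adjusted p = 0.62 with an estimated correlation). Cebpb fell by 1.29 ± 0.23 and Nmrk2 by 1.96 ± 0.36, the latter by 1.09 without the 3 libraries and DEX mouse 4. In all 1258 genes changed, 4404 without the 3 libraries, and without DEX mice 3 and 4 and treated mice 1 and 3 there were 701, 711, 692 and 795. With JGT03 at 400 mg/kg Lars2 rose by 1.96 ± 0.47 (adjusted p = 0.0209), though not without DEX mouse 3 or 4 or treated mouse 4 (adjusted p = 0.0504, 0.0664 and 0.0597). Cebpb, Eng and the membrane gene Mall fell by 1.21 ± 0.23, 0.77 ± 0.13 and 1.28 ± 0.21. Proteasome subunits rose in 3 of 31 (5 adjusted over the list alone; adjusted p = 2.89e-08, adjusted p = 0.689 with an estimated correlation). Glucocorticoid receptor targets fell in 7 of 38 (7 adjusted over the list alone; adjusted p = 0.00209, adjusted p = 0.31 with an estimated correlation). In all 453 genes changed, 4035 without the 3 libraries. There were 229 and 176 without DEX mice 3 and 4 and 148, 165, 133 and 200 without treated mice 1, 2, 4 and 5. With the set as a term edgeR called 0 genes, so neither Lars2 nor any other, in each of these groups (1579 and 1220 at an unadjusted p below 0.05). For the 1258 and 453 genes the median log2 size went from 0.47 to 0.40 and from 0.51 to 0.39, the median SE from 0.123 to 0.206 and from 0.131 to 0.219. Of them 97.4% and 97.8% kept their sign. Eng stayed at -0.96 with an SE of 0.22 at 100 mg/kg, whereas Cebpb went to -0.37 ± 0.35.

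With JGT04 at 100 mg/kg Lars2 rose by 2.13 ± 0.47 in SO (adjusted p = 0.0041, n = 5 and 4), Ucp3 by 1.39 ± 0.35 and the adhesion gene Amigo3 by 1.05 ± 0.23, and the amino acid transporter gene Slc38a2 fell by 1.09 ± 0.16. Endothelial markers fell in 8 of 15 (11 adjusted over the list alone; adjusted p = 5.49e-11, adjusted p = 0.299 with an estimated correlation), Eng by 1.17 ± 0.13, and Col4a2 fell by 1.11 ± 0.18. Of 14 Schwann cell and nerve markers 9 fell (13 adjusted over the list alone; adjusted p = 1.18e-05, adjusted p = 0.89 with an estimated correlation). In all 1326 genes changed, 4583 without the 3 libraries. There were 851 and 613 without DEX mice 3 and 4 and 745 and 785 without treated mice 4 and 5. With JGT04 at 400 mg/kg the detoxification genes Gstt1 and Adh1 rose by 1.39 ± 0.23 (adjusted p = 0.000457, n = 4 and 4) and 1.07 ± 0.18 and Slc46a3 by 0.89 ± 0.15. Eng, Cebpb and Clock fell by 1.03 ± 0.14, 1.57 ± 0.25 and 0.66 ± 0.10. Of the endothelial markers 3 of 15 fell (7 adjusted over the list alone; adjusted p = 2.64e-06, adjusted p = 0.891 with an estimated correlation). Proteasome subunits rose in 3 of 31 (6 adjusted over the list alone; adjusted p = 1.53e-06, adjusted p = 0.891 with an estimated correlation). In all 678 genes changed, 3261 without the 3 libraries. There were 189 without DEX mouse 4 and 381, 318 and 247 without treated mice 1, 2 and 4, and 38 in a fit of only these 2 groups. With the set as a term 4 genes changed at 100 mg/kg, Eng among them (-1.17 ± 0.22, adjusted p = 0.0219). At 400 mg/kg there were 0 by edgeR (1160 at an unadjusted p below 0.05), where without the 3 libraries 5 did. With that term and all libraries Cebpb stood at -0.64 ± 0.36 and Clock at -0.32 ± 0.15. For the 1326 and 678 genes the median log2 size went from 0.51 to 0.41 and from 0.50 to 0.35, the median SE from 0.134 to 0.225 and from 0.127 to 0.201.

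Averaged over the 6 extract groups in SO, endothelial markers fell in 11 of 15 at a median of -0.49 (13 adjusted over the list alone; adjusted p = 6.31e-14, adjusted p = 0.119 with an estimated correlation). Eng fell by 1.01 ± 0.09 (adjusted p = 3.5e-09, n = 29 and 4), also with the set as a term (-1.01 ± 0.17, adjusted p = 0.00271), Pecam1 by 0.64 ± 0.09, Col4a2 by 0.90 ± 0.13 and Cebpb by 0.91 ± 0.17 (-0.24 ± 0.26 with that term). Nedd4 rose by 0.34 ± 0.07, also with the set as a term (0.52 ± 0.11, adjusted p = 0.0269). Slc46a3, Gpam and Lrrc61 rose by 0.78 ± 0.12, 1.19 ± 0.29 and 0.76 ± 0.16. Lars2 rose by 1.51 ± 0.40, less than in any JGT03 or JGT04 group (1.95 to 2.47). Those groups lie in a later set than DEX, so for Lars2 treatment and set cannot be told apart. Schwann cell and nerve markers fell in 12 of 14 at a median of -1.15, Mag by 1.51 ± 0.31 (14 adjusted over the list alone; adjusted p = 6.01e-08, adjusted p = 0.752 with an estimated correlation). Autophagy genes rose in 8 of 33, Lamp1 by 0.27 ± 0.06 (10 adjusted over the list alone; adjusted p = 6.26e-06, adjusted p = 0.472 with an estimated correlation). Inflammatory genes fell in 10 of 21 (12 adjusted over the list alone; adjusted p = 1.93e-05, adjusted p = 0.752 with an estimated correlation). Their median went from -0.40 to -0.20 without the 3 libraries and DEX mouse 4 (adjusted p = 0.0373), and that of macrophage markers, which did not pass, from -0.61 to -0.42 (adjusted p = 0.0688 and 0.17). The chemokine genes Ccl6 and Ccl9, the metallothionein gene Mt2 and the protease inhibitor gene Timp1 fell by 3.28 ± 0.68, 3.28 ± 0.63, 2.89 ± 0.53 and 2.71 ± 0.66, but without DEX mouse 4 they stood at 0.55, 0.12, -0.22 and 1.09 and did not pass. In all 2059 genes changed, 780 up and 1279 down, and 5825 without the 3 libraries. There were 1209 without DEX mouse 3, 925 without DEX mouse 4 and 5355 without JGT02 100 mg/kg mouse 5. The set as a term left 76 calls. For the 2059 the median log2 size went from 0.43 to 0.38 and the median SE from 0.109 to 0.177, with 98.4% keeping their sign.

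RSV in SO raised proteasome subunits, 14 of 31 and none down, Psmd13 by 0.30 ± 0.06 (adjusted p = 0.000994, n = 5 and 4) (18 adjusted over the list alone; adjusted p = 3.91e-09, adjusted p = 0.732 with an estimated correlation). Lars2 rose from 60.7 ± 9.34 to 238 ± 86.6 CPM (log2 1.97 ± 0.47), Amigo3 by 0.97 ± 0.23 and the growth signalling inhibitor gene Pik3ip1 by 0.95 ± 0.23. Matrix genes fell in 7 of 38, Col4a2 by 1.19 ± 0.18 (12 adjusted over the list alone; adjusted p = 4.03e-08, adjusted p = 0.869 with an estimated correlation). Cebpb, Eng and Clock fell by 1.47 ± 0.23, 1.08 ± 0.13 and 0.61 ± 0.09. Of 14 Schwann cell and nerve markers 2 fell (13 adjusted over the list alone; adjusted p = 0.000834, adjusted p = 0.869 with an estimated correlation). The deacetylase gene Sirt1, whose protein resveratrol has been reported to activate, fell by 0.38 ± 0.12 (adjusted p = 0.036), but not without DEX mice 2, 3 or 4 (adjusted p = 0.0745, 0.0525 and 0.155) or RSV mice 1 or 3 (0.0993 and 0.0957). In all 1876 genes changed, 5390 without the 3 libraries. There were 811 without DEX mouse 4 and 1159 and 1233 without RSV mice 3 and 4. When the set was a term 3 changed, and Psmd13 stood at 0.25 ± 0.10 and Eng at -1.08 ± 0.22 (adjusted p = 0.0563), Cebpb at -0.55 ± 0.35 and Clock at -0.27 ± 0.14. For the 1876 the median log2 size went from 0.49 to 0.33 and the median SE from 0.13 to 0.215.

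**Figure D3:**
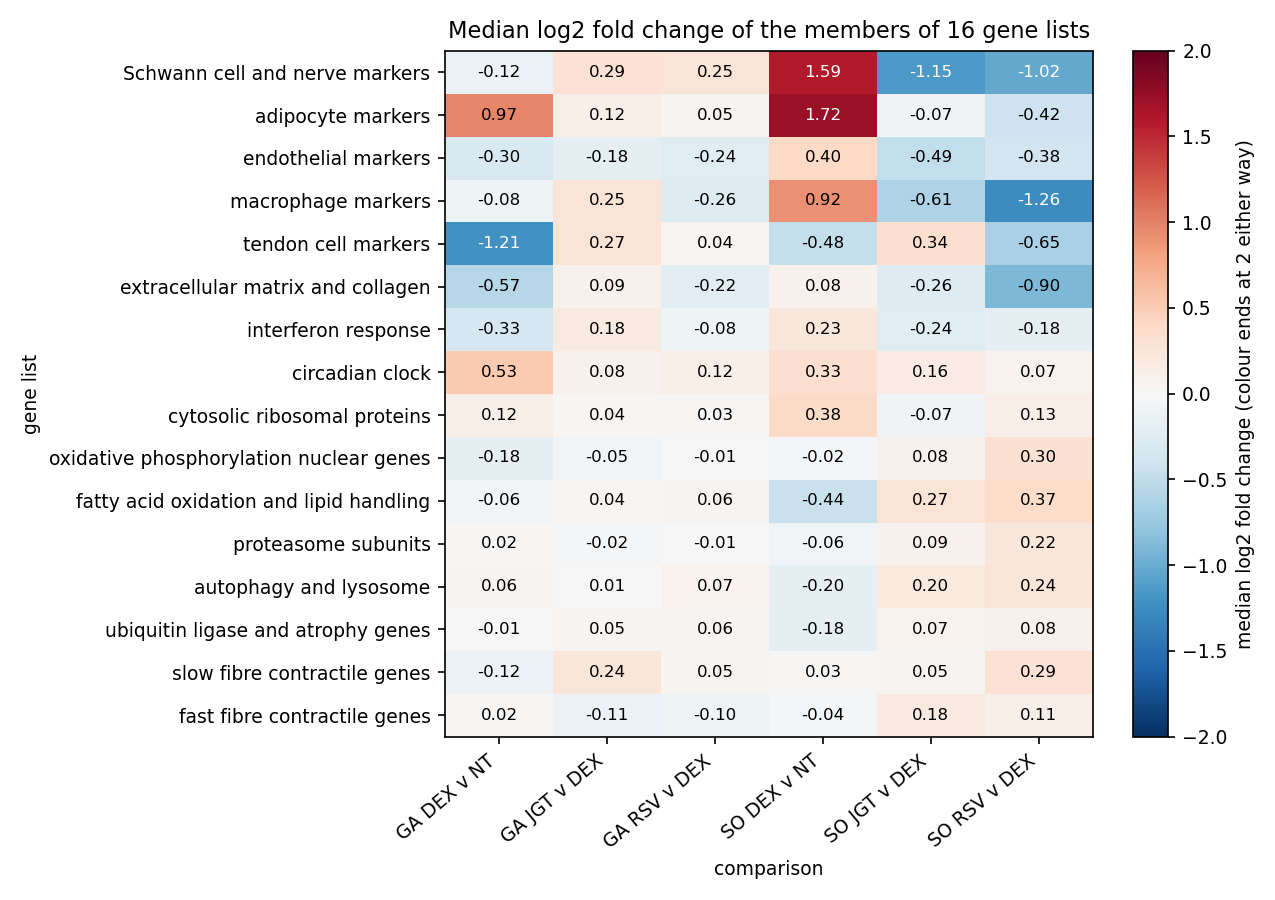
Median log2 fold change (colour and printed value) of the members of 16 gene lists (vertical axis) in 6 comparisons (horizontal axis). The endothelial list was lower in soleus with the 6 extracts (median -0.49) and higher with DEX against non-treated (0.40).

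The change with treatment was also compared between the muscles, SO minus GA. For the mean of the extracts Cebpb differed by -1.30 ± 0.24 (adjusted p = 0.000527) and the adhesion gene Amigo1 by 0.72 ± 0.14 (adjusted p = 0.00146). Amigo1 passed with the set as a term (1.01 ± 0.19, adjusted p = 0.00583) and Cebpb did not (-0.49 ± 0.29, adjusted p = 0.468). Smad3 differed by 0.62 ± 0.15, and Lars2 by 1.50 ± 0.40 but not without GA DEX mouse 4 (1.29, adjusted p = 0.0778). Schwann cell and nerve markers were lower in 9 of 14, Mag by 1.89 ± 0.42 (14 adjusted over the list alone; adjusted p = 7.78e-11, adjusted p = 0.803 with an estimated correlation). In all 667 genes differed, 44 with the set as a term. There were 385, 439, 353 and 394 without GA DEX mice 1 to 4, 344 without SO DEX mouse 3, 1056 without GA JGT02 100 mg/kg mouse 1 and 2264 without SO JGT02 100 mg/kg mouse 5. For RSV Cebpb differed by -2.60 ± 0.30 (adjusted p = 1.25e-08), Lars2 by 2.36 ± 0.50, the focal adhesion gene Nedd9 by -1.44 ± 0.30, the phosphatase gene Lhpp by 0.90 ± 0.19 and the secretory kinase gene Fam20c by 0.81 ± 0.18. Proteasome subunits were higher in 5 of 31, Psmd13 by 0.36 ± 0.07 (10 adjusted over the list alone; adjusted p = 8.3e-11, adjusted p = 0.915 with an estimated correlation). In all 384 genes differed. With the set as a term edgeR called 0 (663 at an unadjusted p below 0.05), when Cebpb stood at -1.10 ± 0.45. For the 384 the median log2 size went from 0.51 to 0.31. There were 236 and 225 without GA DEX mice 1 and 4, and 219 and 217 without SO DEX mouse 4 and SO RSV mouse 3.

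A DEX score was made per library as the mean log2 level of genes that rose less that of genes that fell in all DEX-treated groups together, set to 0 in non-treated mice. It used 3071 genes in GA and 2641 in SO, and stood at 0.849 ± 0.028 in GA DEX and 1.124 ± 0.044 in SO DEX (SD, n = 4 each). A two-sided exact permutation test compared each treated group with DEX, with adjusted p over 14 comparisons. In GA the score was higher than with DEX alone by 0.142 with JGT03 at 400 mg/kg, 0.144 with JGT04 at 100 mg/kg and 0.163 with RSV (exact adjusted p = 0.037 each). In these 3 each treated library stood above each DEX library. The RSV libraries and mice 4 and 5 of JGT04 at 100 mg/kg lie in a later set than DEX, and the score test takes no account of the set. Leaving out any 1 of the 9 libraries of a comparison kept the differences at 0.133 to 0.179. The exact adjusted p was then 0.05 to 0.0625, from the smallest p that the fewer splits can give. Without its mouse 1, GA JGT02 at 100 mg/kg passed at 0.081 (exact adjusted p = 0.0444). In SO no group passed. JGT02 stood lower by 0.252 at 100 and 0.31 at 400 mg/kg (exact adjusted p = 0.05 for the latter) and JGT04 at 400 mg/kg higher by 0.279 (0.05). Without JGT02 100 mg/kg mouse 5 the first passed at -0.403, and RSV passed at 0.151 without RSV mouse 1 (exact adjusted p = 0.0444 each). With the score genes of GA, JGT02 at 100 mg/kg in SO was higher than DEX by 0.127 (exact adjusted p = 0.037) and JGT02 at 400 mg/kg stood at 0.147 (0.0833). The genes of the score come mostly from treated groups, which favours a high score in them. Taken from genes called in DEX against non-treated alone, a choice that favours a high score in the DEX group itself, the score was lower in each GA treated group, by 0.1 to 0.21, and in SO by 0.367 to 0.899. No treated group in GA had a lower score than DEX alone with both gene choices.

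**Figure D4:**
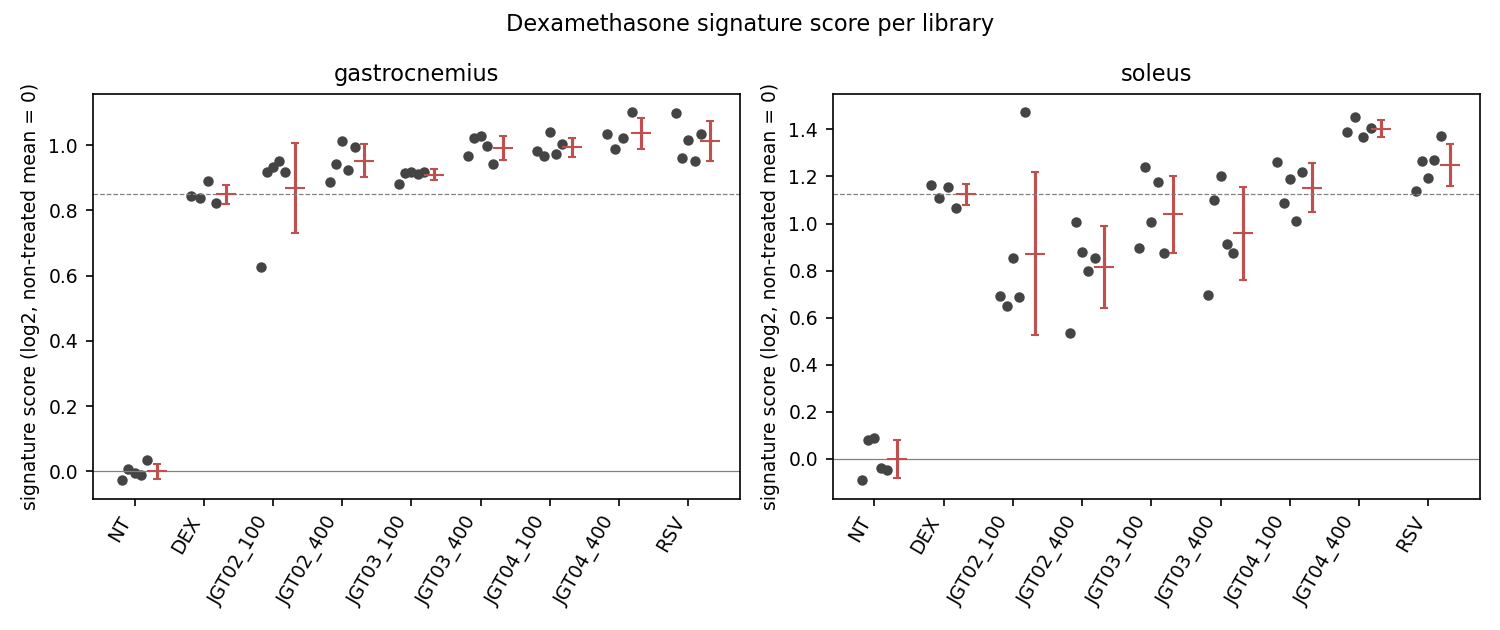
DEX score of each library (points; vertical axis, log2, non-treated mean 0) with mean and SD (red), by group (horizontal axis), for gastrocnemius and soleus. The dashed line marks the mean of the DEX group, 0.849 in gastrocnemius and 1.124 in soleus.

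Because the DEX libraries take part in both comparisons, genes raised by DEX will tend to look lowered by a treatment. Of the 2059 genes called for the extracts in SO, 1172 were called in the opposite direction for DEX against non-treated and 8 in the same direction; 218.6 opposite calls would arise if the lists were independent. When 2 DEX libraries entered one comparison and the other 2 the other, a median of 151 opposite calls was left over 6 divisions (23 to 194). No number expected by independence is given for these smaller lists. Simulated data without any effect gave 0, but they do not show what sharing yields when DEX has an effect. In GA 46 genes were opposite with all libraries and a median of 3.5 with the DEX libraries divided. With RSV in SO 689 were opposite with all libraries and 99 with the libraries divided. Across genes the covariance of the log2 changes for the extracts in SO was -0.18, against -0.0587 in simulated data with the same sharing and -0.0429 with the libraries divided. In GA it was -0.0406, against -0.0453 and -0.01. No claim of a reversal of DEX effects is made from these overlaps.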

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

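The tests of cell mixing, of an extract acting on every mouse, of read shortage, of the macrophage signal, of the fibre share and of treatments as the cause of the library order were chosen only after the result was seen. A single library lay far from the rest of its group in 17 of 118 groups of values, where chance gives about 1 in 20.

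The median correlation with the other libraries of the group was the lowest, and far from theirs, for GA DEX mouse 4 (0.9892), GA JGT02 100 mg/kg mouse 1 (0.7314) and GA JGT04 100 mg/kg mouse 1 (0.9938). In SO this held for DEX mouse 4 (0.952), JGT02 100 mg/kg mouse 5 (0.6509), JGT02 400 mg/kg mouse 1 (0.9234), JGT03 100 mg/kg mouse 3 (0.9831) and JGT04 400 mg/kg mouse 2 (0.9887). The DEX score stood apart in GA JGT02 100 mg/kg mouse 1 (0.625), GA JGT03 100 mg/kg mouse 1 (0.88) and SO JGT02 100 mg/kg mouse 5 (1.474). SO non-treated mouse 1 had the highest total of its group (31.53 M counts) and the highest Myh4 (1138 CPM). SO non-treated mouse 4 had the highest Fbxo32 (547.3 CPM) and Tsc22d3 (61.96 CPM). GA DEX mouse 4 had the highest Igf1 (53.1 CPM) and the lowest Klf15 (10.75 CPM). The change differed between the muscles, by an interaction test, in 1282 genes for DEX, 667 for the mean of the extracts and 384 for RSV. Among 43 genes named for DEX it differed in Chd9 (-1.17), Gpam (-1.88), Mmp19 (2.75), Mybph (4.05), Taco1 (-1.33) and Ucp3 (-1.54), as log2 SO minus GA.

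GA JGT02 100 mg/kg mouse 1 and SO JGT02 100 mg/kg mouse 5 held high Myh3 and macrophage markers. Immune or connective tissue cells alone cannot account for this, because Myh3, Myh8 and Tmem8c, genes of new or fusing fibres, were at least 8.73 times the highest other library of the muscle in all 5 ratios measured (Myh3 and Myh8 share 11.1% and 18.6% of their 31-base words with other genes). An extract acting alike on every mouse is argued against, since the other 4 mice of each group had at most 1.7 times the median Myh3 of the other groups. A shortage of reads is argued against as well, with at least 4 libraries of the same muscle holding fewer counts. Local damage with regeneration, or tissue from elsewhere under these labels, may be behind the pattern, and neither these nor a part of the treatment in some mice was tested.

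Nerve and other cell markers were higher in the SO DEX libraries than in the treated groups. Of the 2059 genes called for the extracts, 1635 passed without DEX mouse 4 and the 3 libraries. That fit cannot decide whether the macrophage signal of DEX mouse 4 is the whole cause, because leaving out the 3 libraries alone raised the count to 5825. With macrophage markers as a covariate 1809 of the 2059 passed, and the median log2 size went from 0.43 to 0.37. That fit holds the SO library high in Myh3 and these markers, so it cannot decide either. Leaving out DEX mouse 4 alone left 925 calls. A lower share of fibres as the only change is argued against, because tendon markers had a median of -0.48 in DEX against non-treated while nerve markers stood at 1.59. Tendon markers also fell with DEX in GA, so a lower share of fibres beside a fall of these genes stays open. Nerve tissue dissected with the soleus cannot be told apart from an effect of treatment, since with the nerve markers as a covariate 49.8% of the calls remained, and this covariate follows the groups. With the nerve covariate the median log2 size of the 2059 genes went from 0.43 to 0.37 and the median SE from 0.109 to 0.119, so calls ended through both, and 2032 genes kept their direction.

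Cebpb and other genes changed level along the listed order of the libraries, inside GA JGT04 100 mg/kg and SO JGT02 400 mg/kg. Cebpb of mice 4 and 5 lay outside the range of mice 1 to 3 in 2 of 2 groups that each got 1 treatment, but the breaks were placed from this gene, so this test leaves the treatments as the whole cause open. Libraries made in sets could give a correlation across genes of the change inside a group with that between the groups around it. It was 0.336 over 7500 genes in GA (highest other division 0.231) and 0.53 over 7734 in SO (0.187). The set term itself called 0 genes in GA and 5 in SO (343 and 1389 at an unadjusted p below 0.05). No label names such sets, which run along with the treatments, so effects cannot be told apart.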

How the results depend on the processing

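The fits without libraries and those with the set in library order as a term were chosen after the data were seen, and the other alternatives beforehand. Counts of changed genes are given in 1 order. For each muscle the order is DEX against non-treated, then against DEX the groups JGT02 at 100 and 400, JGT03 at 100 and 400, JGT04 at 100 and 400 mg/kg, RSV and the mean of the extracts, then the dose and the extracts as a whole. In that order the counts reported from all libraries were 1214, 1478, 117, 3, 98, 200, 295, 199, 182, 29 and 109 in GA, and 3079, 1306, 2532, 1258, 453, 1326, 678, 1876, 2059, 0 and 1775 in SO. The 4 comparisons of the muscles follow as SO against GA in non-treated mice, then SO minus GA for DEX, the mean of the extracts and RSV, at 7016, 1282, 667 and 384. Where a count differs by more than 1.5 times, the cause was not tested except where the way the fit is made shows it.

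DESeq2 size factors changed 1 count by over 1.5 times, that of the GA dose, to 19. The DESeq2 test gave 1356, 751, 168, 12, 162, 327, 399, 301, 262, 118 and 179 in GA, 3304, 1385, 2711, 1447, 747, 1490, 859, 2102, 2107, 0 and 2132 in SO, and 7020, 1688, 823 and 544 between the muscles. With no filter on low counts more genes share the adjustment, and the counts were 879, 1229, 48, 3, 39, 101, 136, 97, 101, 15 and 38 in GA. In SO they were 2221, 906, 1848, 752, 172, 796, 349, 1190, 1618, 0 and 1180, and between the muscles 6559, 778, 299 and 154. Fits of only the groups compared, which hold fewer libraries and their own estimate of spread, gave 2720, 0, 284, 39, 590, 723, 864, 735, 124, 19 and 19 in GA. In SO they gave 4129, 0, 490, 1127, 436, 1619, 38, 2316, 1444, 0 and 1052, and between the muscles 8441, 3458, 398 and 923. Both JGT02 groups at 100 mg/kg fell to 0 by edgeR there, where the group's own spread includes the mouse with high Myh3.

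The labels do not say whether mouse numbers pair the samples, and the values gave little sign of it. Libraries of different groups with the same number had deviations from their group means that correlated at a median of 0.007 in GA and 0.003 in SO, against -0.003 and 0.007 for other numbers. Of 43 GA libraries 9 correlated best with the SO library of their own number, 4 of them with JGT04 at 100 mg/kg, and own numbers had a median of -0.005. With the number as a replicate block the counts were 1183, 73, 87, 2, 62, 168, 285, 155, 150, 33 and 36 in GA and 3460, 1059, 2982, 1361, 594, 1480, 582, 2082, 2345, 0 and 1519 in SO. With the group and number as a replicate block across the muscles they were 6626, 733, 280 and 176. With the block 271 list calls passed, 252 of them among the 263.

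Without GA JGT02 100 mg/kg mouse 1, SO JGT02 100 mg/kg mouse 5 and SO JGT02 400 mg/kg mouse 1 the counts were 3811, 139, 823, 169, 936, 1350, 1637, 1367, 1381, 243 and 306 in GA. In SO they were 6353, 5252, 4449, 4404, 4035, 4583, 3261, 5390, 5825, 0 and 3294, and between the muscles 8801, 5085, 3956 and 3094. Part of this rise follows from the construction, because the common dispersion that all groups share fell in both muscles. Leaving out SO DEX mouse 4 as well gave 5338, 4206, 2955, 2986, 2282, 2790, 1481, 3500, 3665, 0 and 4014 in SO and 9057, 4472, 2558 and 1844 between the muscles. List calls numbered 314 and 283 in these fits, of which 215 and 193 were among the 263. An estimated correlation left 1 list call.

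The set as a term left 1177, 1317, 107, 3, 77, 90, 0, 1, 99, 4 and 0 in GA, 3157, 1335, 2098, 0, 0, 4, 0, 3, 76, 0 and 4 in SO, and 3477, 1295, 44 and 0 between the muscles. Without the 3 libraries and with this term there were 3846, 126, 839, 156, 959, 902, 52, 46, 1020, 126 and 1 in GA. In SO there were 6430, 5380, 2065, 0, 0, 2, 5, 2, 194, 17 and 828, and between the muscles 5827, 5157, 115 and 1. Groups that lie in other sets than DEX are compared through the few groups that span 2 sets, so SEs grow by construction.

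The genes named by rule held 965 calls. Of these 946 passed with DESeq2 size factors, 882 with DESeq2, 807 with the block, 766 without a filter, 890 without the 3 libraries and 574 without these and SO DEX mouse 4. With the set as a term 524 passed, and 507 without the 3 libraries as well. Over all alternatives and omissions 25181 values of these genes were on the same side of the threshold as in the reported fit, 3822 no longer passed, 160 began to pass, 339 moved without a call and 80 changed sign. Of the genes given in the report 3 changed sign. For the mean of the extracts in SO, without DEX mouse 4, Ccl6 stood at 0.55, Ccl9 at 0.12 and Timp1 at 1.09, and Timp1 at 0.43 without the 3 libraries as well. Without JGT02 100 mg/kg mouse 5 they stood at -4.12, -3.99 and -3.43.

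Leaving out 1 library at a time moved the counts over these ranges. In GA they were 871 to 1103 for DEX, 120 (DEX mouse 3) to 2902 (treated mouse 5) for JGT02 at 100, and 39 (DEX mouse 4) to 83 at 400. JGT03 at 100 ranged from 1 (DEX mouse 1, and likewise treated mouse 2) to 3, JGT03 at 400 from 33 (DEX mouse 2) to 68, and JGT04 at 100 from 85 (treated mouse 5) to 178. JGT04 at 400 ranged from 118 (DEX mouse 4) to 238, RSV from 96 (DEX mouse 4) to 154, and the mean from 48 (DEX mouse 4) to 1381 (JGT02 100 mouse 1). The dose ranged from 9 (JGT04 400 mouse 1) to 243 (JGT02 100 mouse 1) and the extracts from 15 (JGT04 400 mouse 1) to 805 (JGT02 100 mouse 3). In SO the ranges were 1981 (DEX mouse 4) to 2761 for DEX, 590 (DEX mouse 3) to 4631 (treated mouse 5) for JGT02 at 100 and 1168 (treated mouse 1) to 2719 at 400. JGT03 at 100 ranged from 692 (treated mouse 1) to 1261 and at 400 from 133 (treated mouse 4) to 679 (DEX mouse 2). With DEX mouse 4 left out JGT04 at 100 and 400, RSV and the mean stood lowest at 613, 189, 811 and 925, and with DEX mouse 2 left out the first 3 stood highest at 1465, 816 and 2152. The mean rose to 5355 and the extracts to 3651 without JGT02 100 mouse 5, and the extracts were lowest at 1230. Between the muscles the ranges were 6503 to 6719, 883 to 1468, 344 (SO DEX mouse 3) to 2264 (SO JGT02 100 mouse 5) and 217 (SO RSV mouse 3) to 540.

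The DEX score depends most on its genes. Taken from DEX against non-treated alone it turned negative for the 7 GA groups in order, at -0.21, -0.166, -0.161, -0.1, -0.153, -0.14 and -0.124. In SO it reversed for JGT04 at 100 (-0.646) and 400 mg/kg (-0.367) and RSV (-0.567), and JGT02 at 400 (-0.899) and JGT03 at 100 (-0.704) and 400 (-0.692) passed. This favours a high score in DEX, and the genes reported one in treated groups. With the genes of the other muscle GA RSV stood at 0.106 (exact adjusted p = 0.0556), and SO JGT02 at 100 and 400 and JGT03 at 100 at 0.127, 0.147 and 0.084. Genes at an adjusted p below 0.01 changed no score call. Without the 3 libraries GA JGT02 at 400 (0.087), JGT03 at 100 (0.065) and JGT04 at 400 (0.158) also passed. So did SO JGT02 at 100 (-0.385) and 400 (-0.242) and JGT04 at 400 (0.193), while JGT04 at 100 stood at -0.021. Leaving out SO DEX mouse 4 as well put these 4 at -0.37, -0.224, 0.186 and -0.02. With 1 library left out GA JGT02 at 100 ranged from 0 to 0.081 (without its mouse 1), JGT03 at 400 from 0.133 to 0.156, JGT04 at 100 from 0.133 to 0.158 and RSV from 0.141 to 0.179. In the last 3 the splits left are too few for an exact adjusted p below 0.05 beside the other comparisons. SO JGT02 at 100 ranged from -0.403 (without mouse 5) to -0.197 and SO RSV from 0.092 to 0.151 (without RSV mouse 1). Opposite calls went from 1172 to 151 in SO and from 46 to 3.5 in GA when the DEX libraries were divided. The limit set by depth was not tested apart from that of spread. At the depth, spread and sample size of DEX against non-treated, simulated 1.5-fold changes were recovered at 52.2% in GA and 62.7% in SO.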

Other observations

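Fits with a set term or without libraries that stood apart were chosen after the results were seen. In non-treated mice 54 of 76 nuclear oxidative phosphorylation genes were higher in SO than in GA and none lower (61 adjusted over the list alone), with Atp5g3 at log2 0.96 ± 0.16 and Ndufb3 at 1.19 ± 0.20 (camera, adjusted p = 1.45e-07, adjusted p = 0.885 with an estimated correlation). Ndufb3 shares 13.5% of its 31-base words with other genes. In SO, DEX raised 6 of 14 smooth muscle and pericyte markers (7 adjusted over the list alone), among them Mcam by 1.15 ± 0.22 and Notch3 by 0.40 ± 0.09 (adjusted p = 0.000548, adjusted p = 0.564 with an estimated correlation). Inflammatory genes rose in 9 of 21 (12 adjusted over the list alone; adjusted p = 0.00265, adjusted p = 0.784 with an estimated correlation), and this list did not pass without the 3 libraries and DEX mouse 4 (adjusted p = 0.23). The chemokine gene Cxcl1 rose by 3.01 ± 0.61, and Osmr by 1.12 ± 0.25 but not without DEX mouse 4 (0.59, adjusted p = 0.0615). With RSV in SO 9 of 21 inflammatory genes fell (11 adjusted over the list alone; adjusted p = 7.35e-05, adjusted p = 0.773 with an estimated correlation), Cxcl1 by 3.17 ± 0.62, or by 2.06 without the 3 libraries and DEX mouse 4. Without the 3 libraries and DEX mouse 4, 5 of 21 fell and the median went from -0.67 to -0.24 (adjusted p = 0.0133), while macrophage markers did not pass (adjusted p = 0.0914). Autophagy genes rose with RSV in 7 of 33 (8 adjusted over the list alone; adjusted p = 8.07e-05, adjusted p = 0.732 with an estimated correlation), including Map1lc3a by 0.52 ± 0.13. Neither Cxcl1 (-2.68 ± 1.19, adjusted p = 0.556) nor Map1lc3a (0.31 ± 0.21, adjusted p = 0.744) passed with RSV in a fit with a set term.

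Up to 100 splits of the libraries into groups of the same sizes, the real one included, asked whether chance gives as many calls. These tests were fixed beforehand. No other split gave as many calls for DEX against non-treated in GA (1214 genes, highest other split 427) and SO (3079, 895). Nor did any for SO against GA in non-treated mice (7016, 3538). This argues against chance alone. In GA no other split reached the real count for JGT02 at 400 (117, 14), JGT03 at 100 (3, 1) and 400 (98, 23), JGT04 at 100 (200, 60) and 400 mg/kg (295, 1), RSV (199, 38), the dose (29, 1) and the extracts (109, 2). In SO the same holds for JGT02 at 400 (2532, 1950), JGT03 at 100 (1258, 455) and 400 (453, 70), JGT04 at 100 (1326, 392) and 400 mg/kg (678, 11), RSV (1876, 377) and the extracts (1775, 286). It holds too for SO minus GA with RSV (384, 295), while with DEX 3 of 100 splits were as large (1282, 1814). The share for the others named here was 1 of 100, or 1 of 35 for JGT04 at 400 mg/kg, the real grouping itself. These shares are not adjusted over the comparisons. Splits exchange libraries of different sets in the listed order, so they cannot tell a treatment from a set.

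Chance could not be excluded in 5 comparisons. For JGT02 at 100 mg/kg 55 of 100 splits in GA gave as many as 1478 (highest other 4308) and 42 in SO as many as 1306 (5728). For the mean of the extracts 14 splits in GA gave as many as 182 (5430) and 11 in SO as many as 2059 (6189). For SO minus GA of that mean 18 gave as many as 667 (4478). The median of the other splits was 1735 in GA and 1021 in SO for JGT02 at 100 mg/kg, and 0 for the mean in GA, in SO and between the muscles. For the SO dose the real count was 0, so 100 of 100 splits gave as many (highest other 1) and decide nothing. Splits with several times the real count point to a structure of the samples. All splits kept the 3 libraries that stood apart, so a count can depend on the side on which such a library fell. In these comparisons the splits cannot tell that from chance. On a scale of slow-fibre genes with the GA median at 0 and the SO median at 1, SO JGT02 100 mg/kg mouse 5 stood at -0.04 and SO JGT02 400 mg/kg mouse 1 at -0.1, the other SO libraries at 0.863 to 1.076. In the latter Myh7 stood at 14.4 CPM, where GA libraries other than the 1 that stood apart ran from 150 to 1130, and Mss51 at 544, where GA libraries ran from 11.1 to 442.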
